A study of Mus musculus with 16 samples.

How the data were processed

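RNA was measured in aortic and pulmonary valves taken by laser microdissection from mouse embryos at stage E14.5. The labels give 4 groups of 4 libraries: wild-type aortic, mutant aortic, wild-type pulmonary and mutant pulmonary valve. The mutants carry a floxed Jag1 allele and Nkx2.5-Cre, which deletes floxed sequence where the cardiac gene Nkx2-5 is active. Per the labels' protocols, PicoPure columns gave the RNA, an Ovation RNA-Seq V2 kit amplified it, and TruSeq reagents made the libraries. Aortic libraries form library batch 1 and pulmonary libraries batch 2, so valve and batch cannot be told apart, while genotypes are compared within a batch. How the captured regions were chosen is not given in the sources used here.

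Per the submitters' processing notes, the tools used were CASAVA 1.8.2, cutadapt 1.6, FastQC and RSEM 1.2.3, with genome build GRCm38. The normalisation and the low-value filter are not given in the sources used here. The deposited table holds a normalised signal for 13964 genes, 1 column per library. Within each library the deposited values are whole multiples of 1 step, and 100% of them gave whole reads at a tolerance of 0.05 read. The deposited scaling differed by at most 0.00042% from trimmed-mean (TMM) factors recomputed with edgeR 4.0.16 from those reads, so the values are CPM rescaled by TMM. They are called normalised counts here. RSEM gives estimated counts, which the recovered whole reads may be after rounding. RSEM also shares reads between near-identical genes, so values of gene copies such as Hmga1b, Rps2-ps10 and Gm9825 are uncertain.

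Recovered reads ranged from 4.56 to 8.68 M per library (M, megareads), with a median of 7.37 M. The mean was 6.76 ± 1.47 M (SD, n = 4) in wild-type aortic, 7.43 ± 1.22 in mutant aortic, 6.37 ± 1.27 in wild-type pulmonary and 7.64 ± 0.434 in mutant pulmonary libraries. The mitochondrial ribosomal RNA mt-Rnr2 took 12.5% to 26.1% of the reads, with the lowest shares in the libraries described below as low in skeletal muscle markers. The libraries were amplified without molecular identifiers that any label mentions, so reads need not be independent molecules. Replicates correlated at r = 0.790 to 0.932 over 24 pairs, and the lowest chi-square per gene between replicates was 24.1, so no pair agreed within sampling noise.

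The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), in 1 model over all 16 libraries with a mean per group, with a mean-variance trend. Genes needed a value of at least 1 in at least 4 libraries, which kept 13963 genes. Tests are two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are on the log2(value + 1) scale and understate the change of low genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, over 24 lists with at least 5 tested members. For the lists that passed in the main model, the correlation estimated from the data was 0.288 to 0.829. The preset does not describe these lists, so their preset p-values are likely too small. The sex-linked list had 1 tested member, Xist, and was not tested. Xist was 0.126 to 1.99 in wild-type aortic library 4, mutant aortic 3, wild-type pulmonary 2 and 4 and mutant pulmonary 1. In the other libraries it was 389 to 2369, so both sexes are present, and sex entered no model. Jag1 also had an exact two-sided permutation test per valve over 70 assignments, whose smallest possible p is 0.0286. The comparisons, tests, gene lists and a first set of alternative settings were chosen before the data were examined.

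The rule for naming genes took Jag1, all Notch pathway members, the 5 genes with the smallest p in each direction where none passed the threshold, and up to 4 members of each list with the smallest p. It left unnamed those predicted genes that have no common name. After the values were seen it was narrowed, to limit length: up to 4 Notch members, up to 4 members of each list past the threshold and, for the mean effect, up to 2 of each other list. Rps2-ps10, Gm9825, Rps2 and genes called only under an alternative were chosen after their values were seen.

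The labels give a litter to each library. Within a valve, wild-type and mutant libraries of the same replicate number share a litter. The libraries come from 5 litters, of which 3 gave both valves. The labels do not tie valves to embryos, so an aortic and a pulmonary library may come from the same embryo. In that case p-values over both valves may be too small. Xist differed between the valves for wild-type replicate 2 and mutant replicates 1 and 3, so these pairs by number are not from the same embryo. Deviations from the group means correlated within litter pairs at 0.48, 0.01, 0.20 and 0.64 in the aortic and 0.49, -0.03, 0.07 and 0.45 in the pulmonary valve. The litter block was an alternative in the first set.

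The others of that set were library weights, litter as a random effect (estimated correlation 0.213), quantile and median scaling, no filter or a mean log2 value of at least 3, pseudocounts of 0.5 and 4, robust variance, cardiomyocyte or erythroid marker means as covariates, each valve alone, camera with an estimated correlation, fry, and leaving out each library. Alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a skeletal muscle marker mean as a covariate, and runs without libraries set apart by their tissue markers. The skeletal muscle and skin marker lists were also chosen after seeing the data.

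The models were tested on simulated data for all 13963 genes, with 50 genes changed at each fold and genes drawn independently. At 2-, 4-, 8- and 16-fold, limma recovered 10%, 78%, 90% and 98% for the aortic valve, 8%, 66%, 92% and 98% for the pulmonary valve, and 30%, 90%, 96% and 100% for the mean effect, with 4, 5 and 10 false calls. For the mean effect, edgeR recovered 38% at 2-fold with 4 false calls, and DESeq2 48% with 39 false calls. A simulated list raised 1.5-fold gave p = 1.1e-21 with the preset and 1.5e-07 with an estimated correlation, and an unchanged list p = 0.722 with the preset.

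Gene positions are from GENCODE mouse release M21 on GRCm38, which matched 13787 of the 13964 identifiers. Sequence similarity was searched with blastn 2.17.0 among its protein-coding transcripts. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.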

Results

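The expression of 13964 genes was measured by RNA sequencing in valve tissue cut by laser from mouse hearts at stage E14.5 (embryonic day), when the outflow valves are growing and being remodelled. Aortic and pulmonary valves came from wild-type embryos and from Jag1flox;Nkx2.5-Cre mutants, with 4 libraries in each of the 4 groups. The comparison asks what loss of Jag1 from cells with Nkx2-5 activity changes in each valve. The mutants carry the Cre as well as the floxed allele, so a genotype difference below need not come from Jag1 loss alone. Jag1 encodes a membrane protein that activates Notch receptors on neighbouring cells. Depth was 4.56 to 8.68 M recovered reads per library (M, megareads). Values below are normalised counts (TMM-scaled CPM), given as mean ± SD with n = 4 libraries per group unless stated, and log2 differences are mutant minus wild type.

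Jag1 transcript was lower in every mutant library than in every wild-type library of the same valve. The gene (ENSMUSG00000027276) is protein-coding and lies on the minus strand of chromosome 2 from 137081456 to 137116644 in GRCm38. In the aortic valve it averaged 33.3 ± 17.1 in wild type and 9.38 ± 2.39 in mutants (log2 -1.62, SE 0.45). In the pulmonary valve it averaged 18.5 ± 5.34 in wild type and 5.68 ± 4.63 in mutants (log2 -1.74, SE 0.45). Each difference had an exact permutation p of 0.0286, the smallest that 70 assignments allow, and also 0.0286 after adjustment over both valves. All 8 litter pairs had the lower value in the mutant. The gene-level value also counts reads from exons that recombination leaves in place, so remaining signal does not measure the uncut allele.

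**Figure D1:**
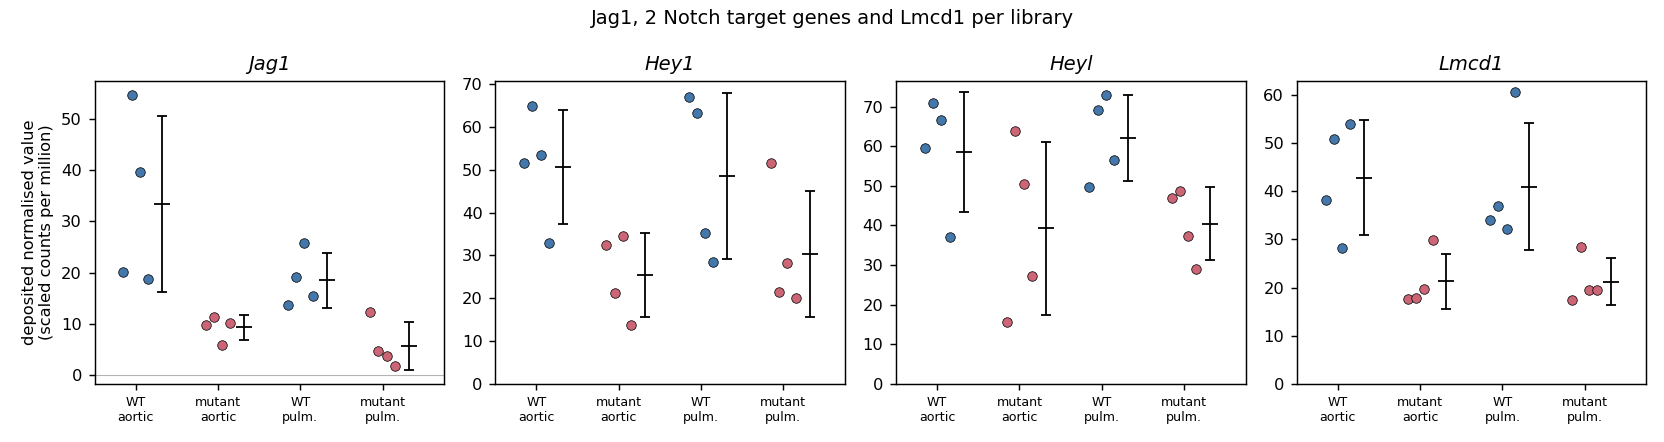
Normalised counts (TMM-scaled CPM) of Jag1, Hey1, Heyl and Lmcd1 in each library, with 4 libraries per group in replicate order from left to right (WT, wild type; pulm., pulmonary valve) and the group mean ± SD beside the points. Jag1 averages 33.3 and 18.5 in the wild-type aortic and pulmonary valve and 9.38 and 5.68 in the mutants.

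The libraries differed in the levels of skeletal muscle and erythroid markers. The mean log2 level of skeletal muscle markers, a list chosen after seeing the data, was at most 2.21 in 6 libraries (wild-type aortic 2 and 4, mutant aortic 4, wild-type pulmonary 2 and 4, mutant pulmonary 4) and at least 5.02 in the other 10. Mylpf, a fast skeletal muscle light chain, was 0.569 in mutant aortic library 4 and 900 in wild-type aortic library 1. Tbx20, a transcription factor of endocardial cushions, was 1032 and 101 in the same libraries. It was 1032 to 1744 in the 6 libraries low in skeletal muscle markers, and it spread widely, from 98.0 to 976, in the other 10. The first principal component held 39.4% of the variance and set those 6 libraries at its positive end. Erythroid transcripts were also uneven, with Hbb-bs (a beta globin) at 16810 in wild-type aortic library 2 and 16659 in wild-type pulmonary library 1 against 3594 or less elsewhere.

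**Figure D2:**
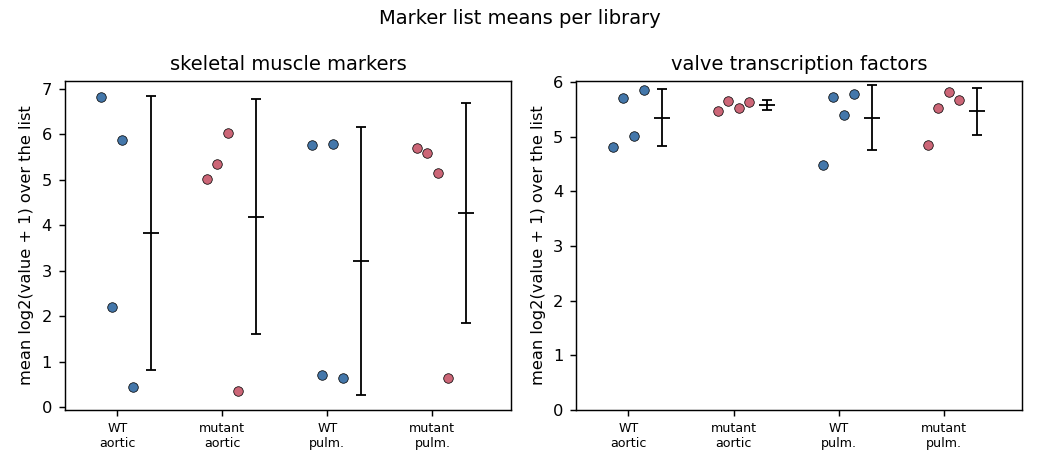
Mean log2(value + 1) of 15 skeletal muscle markers and of 30 endocardial-to-mesenchymal and valve transcription factors in each library, by genotype and valve (WT, wild type; pulm., pulmonary valve), with the group mean ± SD of 4 libraries beside the points. The 6 libraries lowest in skeletal muscle markers lie at or below 2.21 and belong to all 4 groups.

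In the aortic valve, the Notch target genes Hey1 and Heyl, which encode basic helix-loop-helix repressors, had lower mean values in mutants, though neither passed the threshold. Hey1 averaged 50.7 ± 13.3 in wild type and 25.4 ± 9.82 in mutants (log2 -1.01, SE 0.37), and Heyl 58.5 ± 15.1 and 39.3 ± 21.8 (log2 -0.71, SE 0.35), each with the lower value in the mutant of all 4 litter pairs. Vcam1, an adhesion molecule, averaged 18.4 ± 7.13 in wild type and 38.0 ± 12.3 in mutants (log2 1.03, SE 0.35). Of the genes of oxidative phosphorylation, 34 of 43 lay below 0, a group difference past the threshold only at the preset correlation (adjusted p = 0.816 with an estimated correlation).

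None of the 13963 tested genes passed the threshold in the aortic valve with limma (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 196 genes against 698 by chance, and edgeR and DESeq2 also called 0. Among the genes with the smallest p, Neurl3, an E3 ubiquitin ligase, averaged 1.25 ± 0.176 in wild type and 6.62 ± 2.43 in mutants, Usp53 6.87 ± 2.42 and 19.7 ± 4.68, and the sterol oxidase gene Msmo1 13.6 ± 3.69 and 25.9 ± 6.04. Hmga1b, a copy of the chromatin protein gene Hmga1, averaged 4.50 ± 5.10 in wild type and 37.0 ± 19.3 in mutants. On the lower side were Lmcd1, which encodes a cofactor that binds GATA factors, at 42.9 ± 11.9 in wild type and 21.3 ± 5.80 in mutants, and the kainate receptor gene Grik3 at 14.3 ± 6.38 and 4.78 ± 2.97. Zfp867 averaged 14.9 ± 1.73 and 6.65 ± 1.77, and Rsph3b 17.7 ± 5.09 and 8.87 ± 3.03.

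Of the 29 Notch pathway genes tested in the aortic valve, 16 lay below 0 and 13 above, and the list did not pass (camera adjusted p = 0.195). None passed when adjusted over the list alone without the litter block (limma adjusted p = 0.0626 for Jag1 and 0.211 for Hey1), and with the block these 2 did (0.0332 each). Rfng, a glycosyltransferase that modifies Notch receptors, averaged 17.8 ± 3.62 in wild type and 10.6 ± 5.16 in mutants. Oxidative phosphorylation genes fell as a group (camera adjusted p = 0.00808; adjusted p = 0.816 with an estimated correlation), with a median log2 of -0.12. Its members with the smallest p were the complex I gene Ndufs1 at 55.4 ± 3.35 in wild type and 42.6 ± 4.50 in mutants, Atp5g1 at 109 ± 48.5 and 64.9 ± 28.9, Cox4i1 at 211 ± 56.3 and 167 ± 36.4, and Cox6c at 125 ± 14.4 and 105 ± 6.83. The call was lost without wild-type aortic library 1 (adjusted p = 0.470) or 3 (0.990) or mutant aortic library 4 (0.596), and without the 5 libraries lowest on the first principal component the list passed in the opposite direction (adjusted p = 0.0293). It was also lost with the cardiomyocyte marker mean as a covariate (adjusted p = 0.186) and with only the 6 libraries low in skeletal muscle markers (0.0603). Cardiomyocyte markers themselves had 22 of 26 members below 0 in the aortic valve (camera adjusted p = 0.0664). Their mean was log2 2.62 to 3.37 in the libraries low in skeletal muscle markers, apart from wild-type aortic library 2 (4.55), and 4.08 to 6.89 in the others. The list and the covariate thus largely follow that split and need not stand for cardiomyocytes alone. Oxidative phosphorylation means also followed it, at log2 5.82 to 6.13 in the libraries low in skeletal muscle markers and 6.17 to 6.79 in the others. With the litter block 13 lists passed, and 0 of them with an estimated correlation.

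In the mutant pulmonary valve, transcripts of glycolytic and hypoxia-response genes were higher and those of proliferation genes lower as groups, at the preset correlation only (adjusted p = 0.912 for both with an estimated correlation). The proliferation difference rests on wild-type pulmonary library 1, without which it turned upward (adjusted p = 0.833). Pgam1, a glycolytic mutase, averaged 44.6 ± 7.50 in wild type and 79.0 ± 14 in mutants (log2 0.81, SE 0.33), and the hypoxia-induced gene Ankrd37 1.46 ± 1.30 and 7.46 ± 4.31, with the higher value in the mutant of all 4 litter pairs. Mcm6, a subunit of the replicative helicase, averaged 145 ± 39.5 in wild type and 93.1 ± 13.3 in mutants (log2 -0.61, SE 0.20). Erythroid and matrix genes were lower as groups, and ribosomal protein and neuronal genes higher, again at the preset correlation only (adjusted p = 0.912 for each with an estimated correlation), and the erythroid call was lost without wild-type pulmonary library 1 (0.236).

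No single gene passed the threshold in the pulmonary valve with limma (smallest adjusted p = 1.00). There were 437 genes at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 2. The 2 DESeq2 genes were Cd83, a glycoprotein of activated immune cells, at 3.69 ± 2.32 in mutants, and Slain1, a microtubule-associated protein gene, at 5.31 ± 2.07. Both were listed at 0 in all 4 wild-type pulmonary libraries (DESeq2 adjusted p = 0.0112 each). DESeq2 made 39 false calls on simulated data for the mean effect. Nmnat2, an NAD-synthesis enzyme of neurons, averaged 5.26 ± 2.67 in wild type and 23.4 ± 15.1 in mutants, Cnrip1 10.7 ± 1.1 and 26.7 ± 8.35, and Moap1 0.347 ± 0.695 and 6.68 ± 4.43. Slc7a5, a transporter of large neutral amino acids, averaged 39.9 ± 2.43 and 16.4 ± 5.83, Dzip1l 20.8 ± 7.66 and 6.43 ± 2.69, Pyroxd1 35.1 ± 5.21 and 16.1 ± 2.46, and the resolvase gene Gen1 32.3 ± 9.10 and 12.8 ± 2.78.

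Of 24 lists, 6 passed in the pulmonary valve with the preset correlation, and none did with an estimated correlation (adjusted p = 0.912 for each of the 6). Glycolysis and hypoxia genes rose (24 of 25 members above 0, camera adjusted p = 4.1e-06; 0.912 estimated). Aldoc averaged 1.41 ± 2.81 in wild type and 7.15 ± 7.53 in mutants, and Bnip3, a mitochondrial protein gene induced by hypoxia, 19.6 ± 17.9 and 38.5 ± 8.89. Cytosolic ribosomal protein genes rose (44 of 45 above 0, camera adjusted p = 0.000746; adjusted p = 0.912 estimated), with Rpl3, which is 99.8% identical to the pseudogene Rpl3-ps1, at 286 ± 224 and 662 ± 160, Rps13 at 172 ± 62.3 and 242 ± 58.7, and Rps7 at 84.6 ± 36.8 and 122 ± 29.0. Neuronal and Schwann cell markers rose (14 of 16 above 0, camera adjusted p = 0.00199; adjusted p = 0.912 estimated). The neuronal RNA-binding genes Elavl3 and Elavl4 averaged 1.74 ± 2.73 and 4.48 ± 3.12 in wild type and 19.1 ± 26.5 and 21.1 ± 24.3 in mutants, and the autonomic neuron factor Phox2a 1.41 ± 1.55 and 4.38 ± 2.17. This list's call was lost without mutant pulmonary library 1 (adjusted p = 0.256). The 3 pulmonary libraries low in skeletal muscle markers, 2 of them wild type and 1 mutant, had neuronal means of log2 2.23, 1.98 and 2.22, and the skeletal muscle mean averaged 3.22 in wild-type and 4.27 in mutant pulmonary libraries.

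Proliferation genes fell in the pulmonary valve (35 of 42 below 0, camera adjusted p = 0.000105; adjusted p = 0.912 with an estimated correlation). The kinetochore motor gene Cenpe averaged 169 ± 29.7 in wild type and 112 ± 14.1 in mutants, Mcm5 78.3 ± 22.6 and 55.3 ± 8.01, and Top2a 463 ± 118 and 350.2 ± 38.6. Erythroid markers fell (11 of 13 below 0, camera adjusted p = 8.3e-05; adjusted p = 0.912 estimated), with the membrane protein genes Epb42 and Slc4a1 at 15.4 ± 29.6 and 140.3 ± 243 in wild type and 0.310 ± 0.393 and 14.1 ± 7.83 in mutants. Structural matrix genes fell (35 of 41 below 0, camera adjusted p = 0.0133; adjusted p = 0.912 estimated), with Sparc at 1091 ± 337 and 865 ± 333, Col14a1 at 48.0 ± 17.5 and 32.4 ± 18.0, and the hyaluronan synthase gene Has2 at 93.5 ± 54.1 and 58.8 ± 38.1. Wild-type pulmonary library 1 had the highest proliferation and erythroid means and, of its group, the lowest matrix mean. The matrix mean was log2 8.07 to 8.19 in the 6 libraries low in skeletal muscle markers and 6.20 to 7.91 in the others. Of those 6, the pulmonary valve holds 2 wild-type libraries and 1 mutant library. The matrix list lost its call without wild-type pulmonary library 2 (adjusted p = 0.343), 3 (0.144) or 4 (0.495) or mutant pulmonary library 1 (0.597, turned upward). The ribosomal list lost it without wild-type pulmonary library 2 (0.188) or 4 (0.706) or mutant pulmonary library 3 (0.124). It also lost it with the skeletal muscle marker mean as a covariate (camera adjusted p = 0.379). Ribosomal means were log2 8.09 to 8.48 in the 6 libraries low in skeletal muscle markers and 8.64 to 9.30 in the others.

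In the Notch list of the pulmonary valve, 15 of 29 genes lay above 0 and 14 below (camera adjusted p = 0.724). Jag1 was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.0356, and 0.0387 with the litter block). Rbpj, the DNA-binding partner of activated Notch, averaged 95.2 ± 22.0 in wild type and 133 ± 16.3 in mutants, Rfng 12.4 ± 6.46 and 20.1 ± 5.30, and the coactivator gene Maml2 56.0 ± 22.6 and 32.6 ± 10.7.

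Averaged over both valves, mutants had lower mean values of Jag1 (log2 -1.68, SE 0.32), Hey1 (log2 -0.84, SE 0.26) and Heyl (log2 -0.66, SE 0.25). These were the 3 of 29 Notch pathway genes that moved one way in all 8 litter pairs, each lower in the mutant. By chance 0.227 would move either way if the 8 pairs were independent. The pairs come from 5 litters, of which 3 gave both valves, so they need not be independent and the chance count may be higher. Lmcd1 was lower by log2 -0.93 (SE 0.20), also in 8 of 8 pairs. Proliferation and erythroid genes were lower as groups, and glycolytic and neuronal genes higher, at the preset correlation only (adjusted p = 0.817 for each with an estimated correlation). Skeletal muscle markers also had a higher mean in mutants, by log2 0.70 (95% interval -2.30 to 3.70).

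With limma, 0 genes passed for the mean effect, the smallest adjusted p was 0.171, and 389 genes had an unadjusted p under 0.05. edgeR also called 0. With the litter block in limma 2 genes passed, Rps2-ps10 and Gm9825 (adjusted p = 0.0302 each), both annotated as processed pseudogenes, and 99.4% identical over 934 and 843 bases to Rps2 and Rnps1. Both calls were lost with edgeR under the same block (0 genes, 613 at an unadjusted p under 0.05) and with litter as a random effect in limma (0 genes, 663). They averaged 17.0 ± 31.8 and 7.44 ± 14.7 in wild-type aortic, 104 ± 23.5 and 43.9 ± 7.88 in mutant aortic, 13.4 ± 22.4 and 4.03 ± 7.73 in wild-type pulmonary, and 84.2 ± 15.2 and 28.3 ± 2.61 in mutant pulmonary valves. Wild-type aortic library 4 and wild-type pulmonary library 2 held 64.6 and 47.0 of Rps2-ps10, against 2.90 or less in the other 6 wild-type libraries. Without the former 3 genes passed unblocked, and without the latter 2. The ribosomal protein gene Rps2 averaged 391 ± 180 in wild-type aortic and 207 ± 50.2 in mutant aortic valves.

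**Figure D3:**
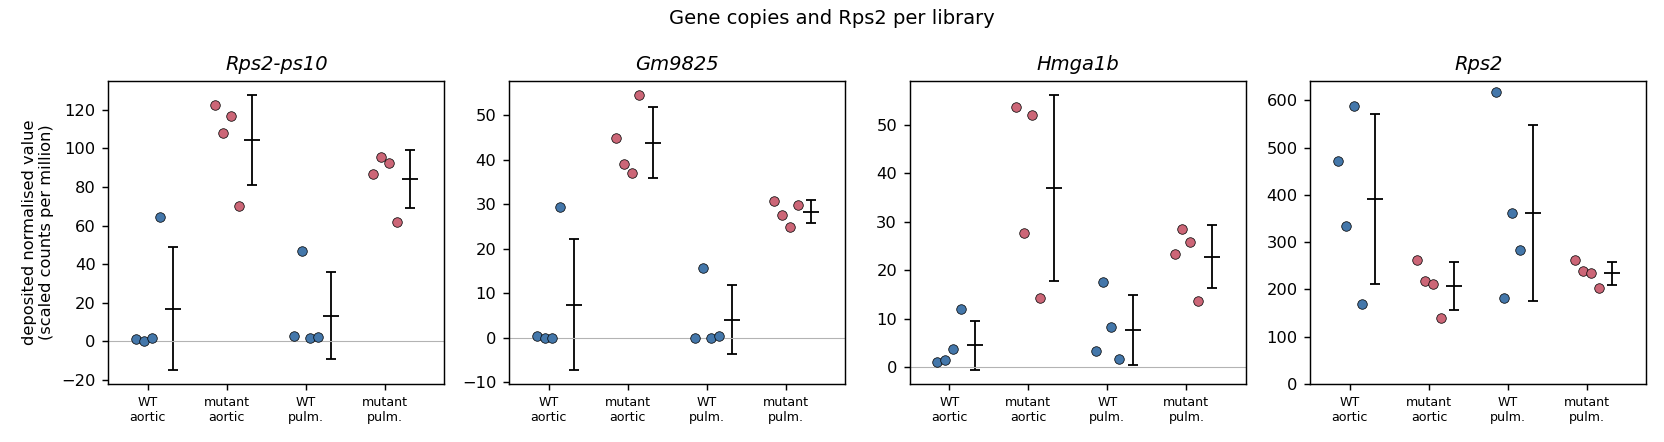
Normalised counts (TMM-scaled CPM) of Rps2-ps10, Gm9825, Hmga1b and Rps2 in each library, with 4 libraries per group (WT, wild type; pulm., pulmonary valve) and the group mean ± SD beside the points, so that bars of skewed groups reach below 0. Rps2-ps10 is 64.6 in wild-type aortic library 4 and 47.0 in wild-type pulmonary library 2, and 2.90 or less in the other wild-type libraries.

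DESeq2 called 5 genes for the mean effect, Jag1 (adjusted p = 0.0134), Lmcd1 and Hmga1b (0.0287 each), Cd83 (0.0380) and Cd74 (0.0402). Cd74, the invariant chain of antigen-presenting cells, averaged 6.20 ± 6.83 in wild-type and 0.833 ± 0.787 in mutant aortic valves, and 6.73 ± 7.21 and 0.971 ± 0.721 in pulmonary valves. It was the 1 macrophage marker of 19 that passed with limma when adjusted over the list alone (adjusted p = 0.0282). Sgk1, a kinase gene induced by steroids, averaged 13.5 ± 2.60 in wild-type and 24.1 ± 3.73 in mutant aortic valves, and 13.3 ± 5.71 and 21.9 ± 2.78 in pulmonary valves. The synaptic vesicle gene Syt4 differed by log2 1.84 (SE 0.47) and Anks1b by 1.65 (SE 0.44), while Slc7a5 differed by -0.85 (SE 0.24) and Dzip1l by -1.04 (SE 0.29).

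Over the Notch list alone, Jag1 passed with limma (adjusted p = 0.00176), and Hey1 and Heyl did not (0.0762 and 0.161). With the litter block all 3 did, at adjusted p = 0.00229 for Jag1, 0.00666 for Hey1 and 0.0383 for Heyl. The whole Notch list did not pass (camera adjusted p = 0.339, 17 members above 0 and 12 below), and Rbpj differed by log2 0.32 (SE 0.16). Counted over all 13963 genes, 119 moved one way in 8 of 8 litter pairs, against 109 by chance if the pairs were independent.

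Proliferation genes fell over both valves (33 of 42 below 0, camera adjusted p = 0.000232; adjusted p = 0.817 with an estimated correlation). Mcm6 differed by log2 -0.46 (SE 0.14), Mcm5 by -0.48 (SE 0.17), Rrm1 by -0.36 (SE 0.20) and Mcm7 by -0.29 (SE 0.16). Glycolysis and hypoxia genes rose (24 of 25 above 0, camera adjusted p = 0.000232; adjusted p = 0.817 estimated), with Ndrg1 at log2 0.64 (SE 0.24) and Pgam1 at 0.53 (SE 0.23). Erythroid markers fell (11 of 13 below 0, camera adjusted p = 0.000526; adjusted p = 0.817 estimated), with the globin gene Hbb-bt at log2 -0.84 (SE 0.64). Neuronal markers rose (14 of 16 above 0, camera adjusted p = 0.00237; adjusted p = 0.817 estimated), with Elavl3 at log2 2.01 (SE 0.78), Elavl4 at 1.31 (SE 0.55), Tubb3 at 0.91 (SE 0.48) and Stmn2 at 0.81 (SE 0.45). Without wild-type pulmonary library 1 the proliferation (adjusted p = 0.505) and erythroid (0.105) calls were lost, and the latter also without wild-type aortic library 2 (0.147). The neuronal call was lost without mutant pulmonary library 1 (0.0643). Neuronal means were log2 1.92 to 2.32 in the libraries low in skeletal muscle markers and 2.29 to 4.75 in the others. Glycolysis and hypoxia means were 4.84 to 5.73 and 5.33 to 6.21. Without the 5 libraries lowest on the first principal component the proliferation list turned upward (0.0597) and the erythroid call was lost (0.0923). With only the 6 libraries low in skeletal muscle markers, where each mutant group holds 1 library, the proliferation list also turned upward.

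Genes whose genotype difference had opposite signs in the valves included Cnrip1, which averaged 24.6 ± 9.34 in wild-type and 13.7 ± 4.78 in mutant aortic valves, and 10.7 ± 1.1 and 26.7 ± 8.35 in pulmonary valves. Ccnf, a cyclin, averaged 21.6 ± 5.11 and 31.5 ± 5.68 in aortic and 43.2 ± 14.2 and 21.2 ± 5.25 in pulmonary valves. Rfng, of the Notch list, averaged 17.8 ± 3.62 and 10.6 ± 5.16 in aortic and 12.4 ± 6.46 and 20.1 ± 5.30 in pulmonary valves. The Jag1 difference had an interaction of log2 -0.12 (SE 0.63), whose sign turned under several alternatives.

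No gene passed for the interaction with limma, edgeR or DESeq2, and 264 had an unadjusted p under 0.05. The interaction was log2 1.98 (SE 0.45) for Cnrip1, 1.77 (SE 0.50) for the DNA-repair gene Paxx, 1.43 (SE 0.44) for Rex1bd and 2.17 (SE 0.67) for the phosphatase gene Pdp2. On the other side it was -1.50 (SE 0.39) for Ccnf, -1.54 (SE 0.41) for LTO1, -1.68 (SE 0.49) for Gen1, -1.46 (SE 0.46) for Cars and -1.11 (SE 0.35) for Tbl2. Of the Notch list, Maml2 had -1.15 (SE 0.50) and Lfng 1.38 (SE 0.65), and the list did not pass (camera adjusted p = 0.651).

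Of 24 lists, 6 passed for the interaction with the preset correlation and 0 with an estimated one (adjusted p = 0.816 for each of the 6). Toward the pulmonary valve stood cardiomyocyte markers (24 of 26 members above 0), cytosolic ribosomal proteins (43 of 45), glycolysis and hypoxia genes (21 of 25) and oxidative phosphorylation (36 of 43). Myl3 and Myh7, ventricular myosin genes, had interactions of log2 2.45 (SE 1.63) and 2.50 (SE 1.78), and Ndufs1 of 0.47 (SE 0.26). The cardiomyocyte mean largely followed the split of the libraries by skeletal muscle markers, so its interaction need not stand for cardiomyocytes. Erythroid markers (11 of 13 below 0) and structural matrix genes (40 of 41) stood toward the aortic valve, with Alas2 at -1.19 (SE 1.08) and Tnc at -0.78 (SE 0.66). Without mutant aortic library 4, or without the 5 libraries lowest on the first principal component, 0 lists passed. With the cardiomyocyte marker mean as a covariate 3 lists passed, and the calls of ribosomal proteins (adjusted p = 0.0712), oxidative phosphorylation (0.178), structural matrix genes (0.175) and cardiomyocyte markers (0.948) were lost.

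In wild-type embryos, 4 lists passed between the pulmonary and the aortic valve at the preset correlation, each with an adjusted p of 0.962 with an estimated correlation, and each call was lost without any 1 of several libraries. Structural matrix genes were higher in the pulmonary valve (40 of 41 above 0, camera adjusted p = 0.000434), a call lost without wild-type aortic library 1 (adjusted p = 0.622) or 3 (0.293) or wild-type pulmonary library 2 (0.122) or 4 (0.133). Erythroid markers were higher (12 of 13, 0.0108), lost without wild-type aortic library 1 (0.0984), 3 (0.0918) or 4 (0.761), and turned downward without wild-type pulmonary library 1 (0.575). Cytosolic ribosomal protein genes were lower (39 of 45 below 0, 9.1e-05), lost without wild-type aortic library 1 (0.311) or 3 (0.758) or wild-type pulmonary library 2 (0.122) or 4 (0.646). Cardiomyocyte markers were lower (24 of 26, 0.0111), lost without the same 4 libraries (0.0611, 0.978, 0.208 and 0.889). No gene passed with limma, edgeR or DESeq2, and 153 had an unadjusted p under 0.05, so no gene is named. The valves were prepared in separate library batches, which cannot be told apart from the valve.

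Across the 13963 genes, the genotype differences in the aortic and pulmonary valve correlated weakly (Pearson r = 0.158, Spearman rho = 0.0770). Genes are not independent replicates, and the aortic and pulmonary libraries share litters. Without wild-type aortic library 4 r was -0.0081, without wild-type aortic library 2 it was 0.012, without mutant aortic library 1 it was 3.5e-05, and without mutant aortic library 4 it was 0.312. Over the 64 genes with an unadjusted p under 0.01 in either valve, among them Jag1, r was 0.457.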

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

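The tests on Rps2-ps10, Gm9825 and Hmga1b, and the skeletal muscle and skin marker lists, were chosen only after the results were seen. Single libraries stood far from the other 3 of their group in 18 of 180 groups examined, where about 1 in 20 does by chance. The value given for each is the gap to the nearest library over the range of the group, on the log2 scale, and each is above Dixon's 95% limit for 4 values.

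Wild-type pulmonary library 1 stood apart in 4 measures. Its mean of proliferation genes was 6.96 against 5.91 to 6.07 in the others (gap 0.845), of structural matrix genes 6.48 against 7.91 to 8.19 (gap 0.840), and of BMP and TGF-beta genes 4.45 against 5.22 to 5.27 (gap 0.936). Anks1b was 1.61 against 0.17 or less (gap 0.896). Mutant pulmonary library 4 was lowest in skeletal muscle markers at 0.65 against 5.14 to 5.71 (gap 0.888), in skin markers at 1.00 against 3.35 to 3.59 (gap 0.908) and in oxidative phosphorylation at 6.13 against 6.50 to 6.52 (gap 0.937). It was highest in EGF and neuregulin genes at 4.94 against 4.80 to 4.82 (gap 0.888). Mutant pulmonary library 3 was highest in erythroid markers at 6.79 against 5.45 to 5.66 (gap 0.843), and library 2 in macrophage markers at 3.09 against 2.69 to 2.72 (gap 0.923).

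In mutant aortic library 4 the Wnt mean was 4.81 against 4.68 to 4.69 (gap 0.922) and Anks1b 0.51 against 2.20 to 2.40 (gap 0.892). Syt4, a synaptic vesicle gene, was highest in mutant aortic library 1 at 3.33 against 2.47 to 2.50 (gap 0.963) and in mutant pulmonary library 1 at 4.87 against 2.38 to 2.69 (gap 0.874). Cd74 was highest in wild-type aortic library 1 at 4.12 against 1.71 to 2.09 (gap 0.844). Rps2-ps10 was highest in wild-type pulmonary library 2 at 5.59 against 1.39 to 1.96 (gap 0.863). Gm9825 was highest in the same library at 4.06 against 0.57 or less (gap 0.858) and in wild-type aortic library 4 at 4.93 against 0.35 or less (gap 0.930).

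The genotype effect differed between valves for 6 gene lists by a test of the interaction at the preset correlation. The camera adjusted p was 0.0142 for cardiomyocyte markers, 9.9e-05 for cytosolic ribosomal proteins, 0.0157 for erythroid markers, 0.0015 for glycolysis and hypoxia genes, 0.00112 for oxidative phosphorylation and 0.0157 for structural matrix genes. Each had an adjusted p of 0.816 with an estimated correlation. The number of lists past the threshold was 1 without wild-type aortic library 1, 2 without wild-type aortic library 3, 3 without wild-type pulmonary library 4 and 0 without mutant aortic library 4.

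Rps2-ps10, Gm9825 and Hmga1b were high in all 8 mutants and in 2 wild-type libraries, aortic 4 (64.6, 29.5 and 11.9 normalised counts) and pulmonary 2 (47.0, 15.6 and 17.6), though Hmga1b was lower, at 13.6, in mutant pulmonary library 4. Higher transcription of Rps2-ps10 with Rps2 unchanged is argued against. Rps2 differed by log2 -0.65 (SE 0.17 with the litter block) and lay -0.70 from the median of its list, the lowest of 45. Higher transcription of Rps2-ps10 beside a separate fall of Rps2 was not tested. In wild type, Rps2 was 169 to 335 in the libraries low in skeletal muscle markers and 362 to 617 in the others. Higher transcription stays open for Gm9825 and Hmga1b, whose relatives Rnps1 (log2 -0.24, SE 0.17) and Hmga1 (-0.45, SE 0.23) lie within 2 SE of 0. Both also lie within 2 SE of the falls expected if the gains of the copies came from them (-0.37 and -0.51). These values thus cannot tell the 2 apart. A candidate explanation is that Cre embryos carry another strain's sequence beside Nkx2-5 on chromosome 17, whose reads match the copies better. The nearest coding relatives, Rps2, Rnps1 and Hmga1 (99.4%, 99.4% and 99.8% identical), lie within 5 Mb of it. The positions of Rps2 and Hmga1 prompted the idea, so only Gm9825 tested it (1 of 1), too few to decide. Under some settings 5 other copies were called, each lower in mutants, and 0 of their nearest coding relatives lie within 5 Mb of Nkx2-5. A tie to Nkx2-5 is thus not shared by every copy called. For mislabelling of these wild-type libraries, 0 of 2 had Jag1 at or below the highest mutant of their valve (18.8 against 11.4 and 19.2 against 12.4). That does not decide it, as 2 libraries are few and wild-type aortic library 4 had the lowest Jag1 of its group. That these controls carry the Cre chromosome stays open and was not tested. In both libraries Rps2 was the lowest of the wild-type group, at 169 and 181 normalised counts, but both are also among the 6 low in skeletal muscle markers, and an effect of Jag1 loss on the copies was not tested apart from the Cre.

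The split of the libraries by skeletal muscle markers, with 4 wild-type and 2 mutant libraries at or below 2.21 and 10 at or above 5.02, was not due to depth. After thinning every library to 4560220 reads a gap of 2.85 remained. Reads from tissue around the valve may explain it, but over the 10 muscle-rich libraries skeletal muscle markers did not correlate with skin (r = -0.0899, rho = -0.0667, permutation p = 0.799, r = 0.079 without the 2 farthest) or neuronal markers (r = -0.135, rho = 0.103, permutation p = 0.705, r = 0.282). These r lie under the 0.5 set in advance, but their 95% limits reach 0.572 and 0.540, a condition added afterwards. They also leave out the 6 muscle-poor libraries, and with them the split to be explained, so they cannot decide its source. Across the split, skin means were 0.80 to 1.22 in 5 of the 6 muscle-poor libraries (2.72 in wild-type aortic 2) and 2.52 to 4.93 in the other 10. Neuronal means were 1.92 to 2.32 and 2.29 to 4.75. Both moved with the split, as reads from other tissue would, but no test of this was set in advance. Genotype alone does not set the split, as both genotypes lie on both sides of it. A partial effect of genotype stays open, with mutants at log2 0.70 (95% interval -2.30 to 3.70, exact permutation p = 0.614 over 4900 reassignments).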

How the results depend on the processing

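The runs with edgeR, DESeq2, a skeletal muscle covariate, 6 or 11 libraries, the litter block with an estimated correlation or over a list alone, and the valve contrast's lists with each library left out were chosen only after the results were seen. Lower Jag1 in the mutant pulmonary valve kept its direction and an unadjusted p under 0.05, from the tool of each run, in all 28 alternatives, and in the aortic valve in 27 of 28. The exception used only the 6 libraries low in skeletal muscle markers (log2 -1.56), which has fewer samples. Leaving out each library gave log2 -1.84 to -1.35 in the aortic and -2.15 to -1.41 in the pulmonary valve. For the mean effect the adjusted p of Jag1 ranged from 0.0134 with DESeq2 to 0.852.

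With those 6 libraries 3 genes were called in the aortic valve, 1 in the pulmonary valve and 3 for the mean effect. The mutant sides then hold 1 library each, assumed to vary like the others. For the mean effect 2 genes were called with the litter block, 2 with the skeletal muscle covariate, 9 with both and 5 with DESeq2. For the pulmonary valve 1 was called with both and 2 with DESeq2. Leaving out each library gave 0 to 2 genes in the aortic valve and 0 to 3 for the mean effect, where wild-type aortic library 4 (2 and 3 without it) and wild-type pulmonary library 2 (2 without it) decided the count. The interaction had 0 genes called in all 35 alternatives, and the valve contrast 0 in all 24.

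The count of gene lists moved most. With an estimated correlation it was 0 in the aortic valve, 0 in the pulmonary valve and 0 for the mean effect, also with the litter block (0, 0 and 0), the skeletal muscle covariate (0, 0 and 0) or both (0, 0 and 0), and with fry it was 0, 0 and 0. At the preset correlation the aortic count of 1 became 13 with the litter block, 11 with the skeletal muscle covariate, 14 with both, 12 without the 5 libraries lowest on the first principal component and 6 with the 6 libraries. The pulmonary count of 6 became 3 with the 6 libraries. The mean-effect count of 4 became 12 with the skeletal muscle covariate, 15 with both and 11 without the 5 libraries.

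Leaving out each library gave 1 to 13 lists in the aortic valve, 4 to 9 in the pulmonary valve and 4 to 7 for the mean effect. The aortic count was 13 without wild-type library 2, 12 without 4 and 2 without 3, and 6, 3, 4 and 3 without mutant libraries 1 to 4. The mean-effect count was 7 without any 1 of wild-type aortic libraries 1, 3 and 4, mutant aortic 4, wild-type pulmonary 1 and mutant pulmonary 2 and 4. Beyond the aortic lists, the litter block added calls of matrix proteases in the pulmonary valve (adjusted p = 0.0179) and the interaction (0.000837), and of smooth muscle (0.0451) and structural matrix genes (0.0158) for the mean effect. With an estimated correlation under the block these were lost too (adjusted p = 0.840, 0.752, 0.700 and 0.718). Adjusted over the list alone, 3 gene results passed without the block and 26 with it, over 4 comparisons. Those it added included Jag1 and Hey1 in the aortic valve (adjusted p = 0.0332 each), Hey1 and Heyl for the mean effect (0.00666 and 0.0383), and neuronal and glycolytic genes in the pulmonary valve. In the valve contrast the count of 4 lists became 1 without wild-type pulmonary library 4, 2 without wild-type pulmonary library 2 or wild-type aortic library 1, 3 without wild-type aortic library 3 and 7 to 13 without the other wild-type libraries, and it stayed 4 without any mutant library.

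The correlation between valves ranged from -0.0081 to 0.312 with 1 library left out, and was 0.457 over the 64 genes with an unadjusted p under 0.01 in either valve, which are selected for large differences. Of 5067 alternative values of named genes, 5030 kept their direction and stayed outside the threshold, 19 passed it and 18 turned. No gene passed in the main model, and most of these were chosen by their small p in it. The count of kept values therefore does not measure how firm the differences are. With the 6 libraries, the log2 difference turned to 0.65 for Slc4a1, -1.19 for Hand1 and 0.25 for Col6a1 in the pulmonary valve, to 0.0059 for Robo4, -0.85 for Gpm6a and -0.0016 for Fbln5 over both, and to 0.10 and 0.24 for Alas2 and Slc25a37 in the interaction. Without the 5 libraries both turned as well, to 0.43 and 0.26. The Jag1 interaction turned to 0.18 with library weights, 0.089 with pseudocount 4, 0.13 with edgeR and 0.16 with DESeq2, and ranged from -0.53 to 0.21 with 1 library left out. The cause of the turns was not tested. Cd83 and Slain1 have no reads in wild-type pulmonary libraries, and whether depth plays a part in this was not tested.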

Other observations

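The search of further gene copies, and the regroupings that count called genes without the litter block, were chosen only after the results were seen. Among gene lists that did not pass for the mean effect, chondrogenic and osteogenic genes had 16 of 22 members above 0 (camera adjusted p = 0.104), among them the cartilage cytokine gene Cytl1 (log2 0.86, SE 0.36) and Runx2, a regulator of bone formation (log2 0.87, SE 0.56). The endocardial-to-mesenchymal and valve transcription factors had 23 of 30 above 0 (adjusted p = 0.195), with Foxc1 at log2 0.51 (SE 0.32) and Snai1 at 0.41 (SE 0.27). Smooth muscle markers had 12 of 16 below 0 (adjusted p = 0.104), with Synpo2 at -0.53 (SE 0.27) and the pericyte proteoglycan gene Cspg4 at -0.46 (SE 0.27). Structural matrix genes had 30 of 41 below 0 (adjusted p = 0.233), with Col1a1 at -0.26 (SE 0.21) and Fbln5 at 0.52 (SE 0.48).

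Of the signalling lists, BMP and TGF-beta genes had 21 of 35 members above 0 (camera adjusted p = 0.233), with the receptor genes Acvrl1 at log2 0.93 (SE 0.43) and Bmpr1b at 1.47 (SE 0.72). FGF and PDGF genes had 10 of 14 above 0 (0.233), with Fgf2 at 1.04 (SE 0.42) and Fgfr4 at -0.56 (SE 0.28). Wnt genes had 22 of 35 above 0 (0.401), with Fzd7 at 0.72 (SE 0.28) and Wnt9a, a ligand made by valve endocardium, at -0.94 (SE 0.38). EGF and neuregulin genes had 14 of 21 above 0 (0.479), with the feedback inhibitors Errfi1 at 0.34 (SE 0.24) and Spry4 at 0.42 (SE 0.30). Semilunar valve and outflow patterning genes had 23 of 35 above 0 (0.253), with Cxcl12 at 0.90 (SE 0.45) and the second heart field factor Isl1 at 0.76 (SE 0.41).

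Btg2, an antiproliferative gene, was lower in the mutant of all 8 litter pairs (log2 -0.71, SE 0.23), while the list of CDK inhibitors and cell-cycle arrest had 10 of 20 above 0 (camera adjusted p = 0.863) and Cdkn2c at -0.42 (SE 0.25). Egr2, an immediate-early factor, was lower in 7 of 8 pairs (log2 -1.43, SE 0.52) and Fos differed by 0.83 (SE 0.39), in a list with 12 of 22 below 0 (0.479). Matrix proteases and inhibitors had 18 of 35 above 0 and a median and mean of opposite sign (0.632), with Adamts15 at -0.54 (SE 0.25) and Lox at 0.37 (SE 0.28). The median and mean of the Notch list and of cardiomyocyte markers also had opposite signs.

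Of cell-type lists, endothelial markers had 15 of 23 above 0 (camera adjusted p = 0.632), with Emcn at log2 0.78 (SE 0.33) and Robo4 at -0.57 (SE 0.31). Epicardial markers had 7 of 9 above 0 (0.551), with Krt19 at -0.89 (SE 0.58) and Gpm6a at 0.79 (SE 0.56), cardiomyocyte markers 13 of 26 (0.676), with Mybpc3 at -1.14 (SE 0.85) and Hspb7 at -0.50 (SE 0.46), and macrophage markers 11 of 19 (0.920), with Mrc1 at 0.69 (SE 0.40). Mitochondrially encoded genes had 13 of 15 below 0 (0.137), with mt-Nd6 at -0.31 (SE 0.15) and mt-Nd2 at -0.28 (SE 0.20). Oxidative phosphorylation had 23 of 43 below 0 (0.479), with Cox7c at 0.32 (SE 0.19) and Ndufa2 at -0.25 (SE 0.19). Ribosomal protein genes had 35 of 45 above 0 (0.300), with Rpl3 higher in the mutant of all 8 pairs (log2 1.19, SE 0.49).

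Other groupings of the same libraries often gave as many genes at an unadjusted p under 0.05, and as many lists, as the genotypes did. For called genes the real count is 0, which every split reaches, so their counts decide nothing: 35 of 35 in the aortic valve (highest other 1), 35 of 35 in the pulmonary valve (0), 35 of 35 in the valve contrast (2039), 100 of 100 for the mean effect (1437) and 100 of 100 for the interaction (2643). Genes at an unadjusted p under 0.05 were matched in 31 of 35 for the aortic valve (real 196, highest other 4006), 18 of 35 for the pulmonary valve (437, 2774), 35 of 35 for the valve contrast (153, 4566), 63 of 100 for the mean effect (389, 4166) and 96 of 100 for the interaction (264, 4824). Lists past the threshold were matched in 34 of 35 for the aortic valve (1, 17), 21 of 35 for the pulmonary valve (6, 16) and 93 of 100 for the mean effect (4, 17). The correlation between valves was matched in 28 of 100 (0.158, 0.669). Chance cannot be excluded for the unadjusted counts, the lists or the correlation.

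Splits that give many times the real count point to a structure of the samples, such as the one seen in Mylpf and Tbx20. Among the 8 splits that part every litter pair, as the real one does, the pulmonary valve's 437 genes were reached by 2 (highest other 446) and its 6 lists by 4 (10), and the aortic valve's 196 genes by 6 (278) and its 1 list by 7 (12). With the litter block, the 2 genes called for the mean effect, Rps2-ps10 and Gm9825, were reached by 1 of 100 swaps within pairs, the real one (highest other 1). That is the smallest share that 100 swaps can give, and it was not adjusted over the regroupings. Both edgeR under the same block and limma with litter as a random effect put the count at 0, so chance is not excluded.

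Under some settings 5 other copies were called, each lower in mutants. For the mean effect in the main model their log2 differences were -3.84 (SE 1.65) for Rps3a3, -3.03 (SE 1.10) for Rps3a2, -3.03 (SE 1.1) for Tpm3-rs7, -2.73 (SE 0.95) for Gm3608 and -1.39 (SE 0.89) for Rpl3-ps1. Their nearest coding relatives are Rps3a1, Rps3a1, Tpm3, Capza1 and Rpl3, of which 0 of 5 lie within 5 Mb of Nkx2-5, on chromosomes 3 and 15.

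Strain sequence linked to the engineered loci may also carry genotype differences, so genes within 10 Mb of Nkx2-5 and of Jag1 were tested. Beside Nkx2-5, 10 of 319 genes (3.13%) had an unadjusted p under 0.05 for the mean effect, among them Rps2, against 2.77% elsewhere (one-sided Fisher's exact p = 0.394, adjusted 0.789). Beside Jag1, 2 of 118 did (1.69%), against 2.79% (one-sided Fisher's exact p = 0.844, adjusted 0.844). Neither shows an excess, and counts this small leave a modest one open.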
